A study of Homo sapiens with 14 samples.

How the data were processed

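Visium CytAssist libraries for formalin-fixed tissue, with RNA probes and the Human Immune Cell Profiling antibody panel, were made from breast tissue per the labels' protocols. Space Ranger was used, with the builds hg38 and GRCh38, per the submitters' processing notes, and its version was 3.0.0 per the file headers. The other read processing steps are not given in the sources used here. The RNA values are raw UMI counts per gene and spot as deposited, without normalization. The antibody values deposited by the authors are not counts but a score: tags per spot multiplied by 10000 over the isotype control tags of the spot plus 1 and truncated to whole numbers, as the deposited factors and the values show. Dividing by the deposited factor gave back whole tags within 0.1 for at least 99.9% of entries of each library. Moran's I per antibody is a score that the authors deposited with each library. No image was used.

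Groups and replicate numbers were taken from the labels: the number names the patient, and the series text says that biopsy and surgical specimen are matched within 6 patients. The fits therefore had the patient as a block. The deviations of the 2 libraries of a patient from their group means correlated with r of 0.191 to 0.429 over all spots and 0.289 to 0.517 in epithelial-rich spots. Each pair correlated best with itself in 4 of 5 and in 5 of 5 patients. The 2 rep libraries are further sections and did not count as replicates. The design fixed before the data were examined had 12 libraries. Pre replicate 2 was then found to be contained spot by spot in post replicate 2, so 10 libraries in 5 pairs were used, and the 12 libraries as deposited became an alternative, as did 12 libraries without the shared spots. Lists, named genes, the choice of epithelial-rich spots and most alternatives were fixed before the data were examined. Chosen after seeing the data were the change to 5 pairs, the alternatives with 12 libraries, edgeR on recovered tags, the protein-RNA relation without 2 antibodies, the rho over markers in both libraries of a pair, the leave-one-out values of the spatial and depth measures, and the tests of explanations in the closing section apart from one named there. Limma as the main test of antibodies was also taken up after the form of their values was seen.

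RNA counts were summed over the spots under tissue of each library, since spots are not replicates. The files hold 18085 genes. Set aside from every test were 21 genes that mark sex or genotype. Epithelial-rich spots were those with at least 200 UMIs, ranked by the share of UMIs on the epithelial list, top 25 percent, and the genes of that list were left out of that test. They summed to 61604 UMIs in the shallowest library, where a gene at 10 CPM would have under 1 count. Genes were filtered with filterByExpr, scaled with trimmed means of M values (TMM) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), post minus pre, with Benjamini-Hochberg adjustment at 0.05. The median gene moved by 0.05 or less on the log2 scale under each of the 3 scalings tried. Alternatives were DESeq2 1.42.0 and limma voom 3.58.1 with sample quality weights, other scalings and filters, thinning of every library to the shallowest total (257356 UMIs over all spots), other choices of spots, the rep libraries, and leaving out each replicate.

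The 34 gene lists, with 416 entries of which 397 are among the genes in the files, were tested with camera (preset correlation 0.01, and estimated) and fry in limma on log2 CPM with a prior count of 2. Lists with fewer than 3 tested members were not tested. Antibodies were assumed beforehand to be counts for edgeR. As the values turned out to be normalized, the main test was limma on log2 of summed antibody tags over the mean of the 4 isotype controls, with the patient as a block, and edgeR on the recovered tags was an alternative. Single measures were compared with exact two-sided sign-flip tests over pairs. Correlations across markers used 10000 permutations. Spots were thinned to 500 UMIs for co-localisation of lists and shallower spots left out, with 1000 and no thinning as alternatives. Without thinning, list shares over all spots with RNA were used. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

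The rule for named genes took up to 10 genes each way past the threshold with a mean log2 CPM of at least 3 and the same direction in all pairs. Where none passed it took the 5 each way with the smallest p. Up to 4 members of each list described and 15 genes fixed by name were added. NR4A1 was named after its values were seen. Results of some genes are not reported here. Symbols are those of the files. RefSeq's table for GRCh38.p14 held 17539 of the 18061 symbols, and positions come from it.

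On simulated counts with 200 changed genes, edgeR called 17.9% of 2-fold, 77.6% of 4-fold and 83.3% of 8-fold changes over all spots (13806 genes), with 11.2% of calls false, and 1 gene when none was changed. In epithelial-rich spots (12048 genes) it called 23.9%, 82.1% and 86.4%, with 5.19% of calls false, and 0 when none was changed. The changed genes were drawn only from genes above a minimum mean count, and genes were simulated independently of each other. These rates therefore need not hold for genes with low counts, for correlated genes or where fewer genes change. For 31 antibodies limma called 56.3% of 2-fold and 82.3% of 4-fold changes and 0.96% of unchanged ones. Counts cover counting error within a library. The spread between patients sets the precision of each comparison.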

Results

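Breast cancer tissue of 6 patients was measured before and after primary endocrine therapy, a treatment that withdraws or blocks estrogen signalling. For each patient a biopsy taken before therapy (group pre) and a surgical specimen taken after it (group post) were profiled with Visium CytAssist, in which probes for most protein-coding genes and barcoded antibodies are captured together on a grid of spots. A spot covers a small area that can hold several cells of different types. The panel held 31 antibodies against immune and tissue markers and 4 isotype controls, antibodies without a specific target that give the background. There were 14 libraries: 6 of group pre, 6 of group post, and 2 further sections filed with post replicates 4 and 5, called rep libraries here. The comparison asks which transcripts and proteins differed between the specimens before and after therapy, and it cannot part therapy from the change from biopsy to surgical specimen.

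All 2256 spots of pre replicate 2 were also present in post replicate 2, with the same barcodes and with 0 differing RNA or antibody entries. Post replicate 2 held 2736 spots more. This pair therefore gave no comparison of independent libraries, and the tests used the other 5 pairs, replicates 1, 3, 4, 5 and 6. The decision was made from the identity of the files, before any test. With 5 pairs an exact sign-flip test cannot give a two-sided p below 0.0625.

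Surgical specimens covered far more of the capture area than biopsies. The 5 biopsies held 929.4 ± 726 spots under tissue (SD, n = 5) and the 5 surgical specimens 4798 ± 260 (SD, n = 5), higher in 5 of 5 pairs (exact sign-flip test, two-sided p = 0.0625, adjusted over 4 measures p = 0.25). Total RNA counts, as unique molecular identifiers (UMIs), ran from 257356 to 2846636 in the biopsies and from 3388458 to 27533893 in the surgical specimens. Depth per spot differed by less than the spread between patients: the median UMIs per spot were 894 ± 974 before and 1247 ± 623 after therapy, higher in 3 of 5 pairs (exact sign-flip test, p = 0.4375). Median antibody tags per spot were 1152 ± 720 and 1335 ± 864 (SD, n = 5), higher in 3 of 5 pairs (exact sign-flip test, p = 0.6875). Mitochondrial transcripts took 5.18% ± 3.68 of UMIs before and 2.31% ± 1.20 after therapy (SD, n = 5), higher after therapy in 1 of 5 pairs (exact sign-flip test, p = 0.1875).

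Within the epithelial-rich spots, 9 genes rose after therapy and 0 fell, and 7 of the 9 belong to the immediate early list, genes that cells switch on within minutes of a stimulus. The transcription factor genes FOSB, ATF3, EGR1 and JUN rose by 5.49 ± 0.69, 4.14 ± 0.52, 4.12 ± 0.58 and 3.25 ± 0.48 on the log2 scale (± SE, 5 pairs). FOSB went from 14.9 ± 17.5 to 555 ± 578 CPM, the counts scaled to library size (SD, n = 5), ATF3 from 23.5 ± 14.5 to 472 ± 314, EGR1 from 73.4 ± 78.2 to 1248 ± 1176 and JUN from 108 ± 21.1 to 1273 ± 835. DUSP1, a phosphatase that turns off MAP kinases, rose by 3.95 ± 0.59, from 58.4 to 930 CPM. CCN1, a matrix protein, rose by 3.22 ± 0.44, and ZFP36, which speeds the decay of cytokine transcripts, by 2.51 ± 0.41. Outside that list, RGS1, a regulator of G protein signalling in immune cells, rose by 2.92 ± 0.36, from 23.9 to 149 CPM.

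Each of the 9 genes was higher after therapy in 5 of 5 pairs. In edgeR's quasi-likelihood test over 12048 genes the adjusted p was 0.00455 for FOSB, ATF3 and RGS1, 0.0105 for CCN1, 0.0108 for EGR1, 0.0156 for DUSP1 and JUN, and 0.036 for ZFP36. FOS and NR4A1, immediate early genes too, had log2 changes of 4.55 ± 0.81 and 5.08 ± 0.92 and did not pass (edgeR adjusted p = 0.0751 and 0.0844). At an unadjusted p below 0.05 there were 340 of the 12048 genes, 215 higher and 125 lower. This is a smaller share than the 0.05 expected if no gene changed. DESeq2 called 29 genes (26 up, 3 down) and limma voom 12 (11 up, 1 down), and each held all 9. Of the 9, only 1 was called in the top 50 percent of spots and 2 where epithelial exceeded fibroblast UMIs. The design as fixed beforehand, with all 12 libraries, called 0 genes in edgeR (296 at an unadjusted p below 0.05), and without the patient as a block 0 were called (155 at an unadjusted p below 0.05). Without replicate 1 the count was 16.

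**Figure D1:**
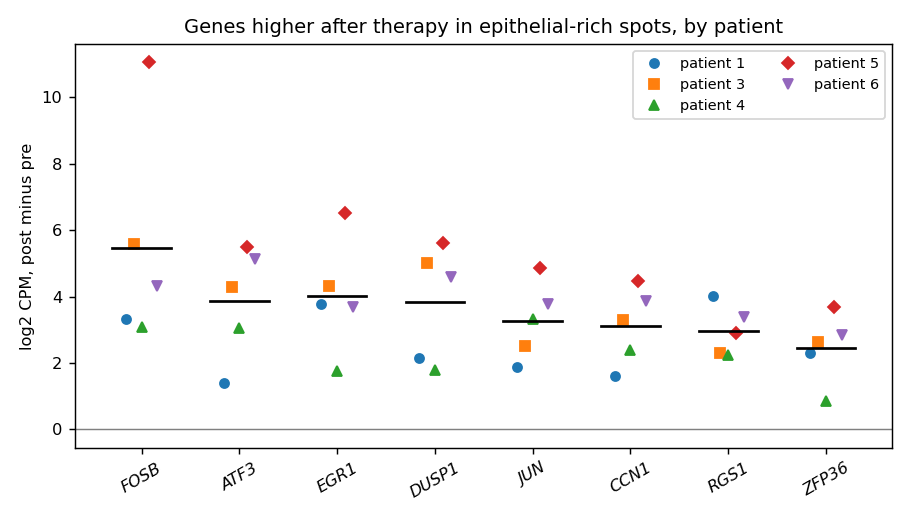
Log2 CPM after minus before therapy (vertical axis) of 8 of the 9 genes past the threshold in epithelial-rich spots, one point per patient and a bar at the mean of 5 patients. All points lie above 0. The FOSB value of patient 5, at 11.06, is the largest and rests on a very low level before therapy.

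The 8 genes named lie on 3 chromosomes, in GRCh38.p14 coordinates of RefSeq. On chromosome 1 are CCN1 (ENSG00000142871, 85580761 to 85583950), JUN (ENSG00000177606, 58780791 to 58784047), RGS1 (ENSG00000090104, 192575773 to 192580024) and ATF3 (ENSG00000162772, 212565407 to 212620777). On chromosome 5 are EGR1 (ENSG00000120738, 138465479 to 138469303) and DUSP1 (ENSG00000120129, 172768096 to 172771195). On chromosome 19 are ZFP36 (ENSG00000128016, 39406847 to 39409407) and FOSB (ENSG00000125740, 45467996 to 45475179). The counts are over probes for each gene, so no exon or variant is resolved.

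Genes of the hormone receptor pathway and of the cell cycle did not pass the test in epithelial-rich spots. The estrogen receptor gene ESR1 had a log2 change of -0.26 ± 0.50 (± SE, 5 pairs), the progesterone receptor gene PGR -0.53 ± 1.01, the estrogen-induced genes GREB1 and TFF1 -1.12 ± 0.71 and 0.61 ± 1.18, and CCND1, which encodes cyclin D1, -0.59 ± 0.42. The proliferation genes MKI67 and TOP2A had changes of 0.16 ± 0.52 and 0.10 ± 0.54, and ERBB2, the gene of the receptor HER2, -0.27 ± 0.33. COL1A1, CD163 and ADIPOQ, markers of fibroblasts, macrophages and adipocytes, had changes of 0.60 ± 0.73, 0.11 ± 0.51 and -1.02 ± 0.97. CD3E and MS4A1 had too few counts to be tested there. In these spots the epithelial list took 0.701% ± 0.389 of UMIs before and 0.713% ± 0.414 after therapy (SD, n = 5), higher in 1 of 5 pairs (exact sign-flip test, p = 1). The fibroblast list took a larger share of the same spots, 2.07% ± 1.73 before and 2.50% ± 1.74 after therapy. It was higher in 4 of 5 pairs (exact sign-flip test, p = 0.6875). Changes in epithelial-rich spots therefore cannot be assigned to epithelial cells alone.

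Summed over all spots, the genes with the smallest p were again higher after therapy, but none passed the threshold. RGS1 had a log2 change of 2.85 ± 0.33 (± SE, 5 pairs; 25.7 to 167 CPM; edgeR adjusted p = 0.0518). DUSP1, ADAMTS1, which encodes a matrix protease, and CCN1 had changes of 3.72 ± 0.58, 1.83 ± 0.29 and 2.93 ± 0.47 (edgeR adjusted p = 0.217 for each). All of these were higher in 5 of 5 pairs. The 5 lower genes with the smallest p were APOL4 (-1.48 ± 0.31, lower in 5 of 5 pairs), the lipid carrier gene APOC1 (-1.74 ± 0.42), GIMAP4, a gene of lymphocytes (-1.15 ± 0.31), PALD1 (-1.03 ± 0.29) and the T cell gene CD2 (-1.19 ± 0.35). The edgeR adjusted p was 0.627 for APOL4 and 1 for the other 4.

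Of 13806 genes tested over all spots, edgeR called 0, with 335 at an unadjusted p below 0.05 (216 higher, 119 lower). Here too the share lay under the 0.05 expected if no gene changed. DESeq2 called 34 (31 up, 3 down) and limma voom 7, all up. Without replicate 1 edgeR called 5 and without replicate 6 it called 1. The log2 changes of FOS and EGR1 were 4.47 ± 0.89 and 3.45 ± 0.60, higher in 5 of 5 pairs (edgeR adjusted p = 0.444 and 0.252). ESR1 had a change of -0.19 ± 0.57, PGR -0.34 ± 0.88, GREB1 -0.68 ± 0.77, TFF1 0.78 ± 1.32, CCND1 -0.58 ± 0.43, ERBB2 -0.17 ± 0.30, MKI67 0.20 ± 0.35 and TOP2A 0.52 ± 0.54. For the stromal markers the changes were 0.46 ± 0.66 for COL1A1 and -1.69 ± 1.24 for ADIPOQ. For the immune markers they were 0.04 ± 0.63 for CD163, -1.02 ± 0.54 for CD3E and -0.73 ± 1.05 for the B cell gene MS4A1. None of these passed (edgeR adjusted p = 0.9998 for each). MS4A1 was nevertheless higher after therapy in 4 of 5 pairs, with 26.5 ± 51.8 CPM before and 4.63 ± 2.03 after (SD, n = 5).

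The immediate early genes moved together. Over all spots 17 of 17 members lay above 0, with a mean log2 change of 2.85, and 16 rose when p was adjusted over the list alone (0 over all genes tested). The mean per patient was 2.78 ± 1.57 (SD, n = 5), above 0 in 5 of 5. In epithelial-rich spots 16 of 16 tested members lay above 0, with a mean of 3.05 and 3.01 ± 1.31 per patient, and 15 rose adjusted over the list alone (7 over all genes). The camera test with a preset correlation called the list in both (adjusted p = 9.82e-31 and 4.56e-27). With an estimated correlation it did not (adjusted p = 0.399 and 0.490 with an estimated correlation). The mast cell list moved in the same direction over all spots, by 0.86 over 5 members, all above 0, with a mean per patient of 0.94 ± 0.43 (SD, n = 5). HDC, which makes histamine, had a change of 1.70 ± 0.51 and rose adjusted over the list alone. MS4A2, CPA3 and GATA2 had changes of 1.13 ± 0.46, 0.62 ± 0.28 and 0.69 ± 0.34 (camera adjusted p = 0.000616, and adjusted p = 0.399 with an estimated correlation). The level of the immediate early list also differed between libraries filed with the same specimen: the rep library lay 2.26 above the first section for one specimen and 3.96 below it (-3.96 on the log2 scale) for the other.

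Heat shock genes, which encode chaperones, lay above 0 for 8 of 9 members over all spots, with a mean of 0.71, and 3 rose adjusted over the list alone. DNAJB1, HSPA1A and HSPA1B had changes of 1.18 ± 0.31, 1.38 ± 0.39 and 1.27 ± 0.44 (camera adjusted p = 4.13e-05, and adjusted p = 0.527 with an estimated correlation). Counts of HSPA1A and HSPA1B are uncertain, since the 2 genes are near copies. Of the 10 genes of cell cycle arrest, 3 rose adjusted over the list alone in both analyses: GDF15, a stress cytokine (2.27 ± 0.58 over all spots), TOB1 (1.04 ± 0.28) and CDKN1A, which encodes the CDK inhibitor p21 (1.27 ± 0.42). The list itself was not called (camera adjusted p = 0.218). The MAPK feedback list had a mean of 0.22 over all spots, with 0 members past the list-alone threshold and DUSP5 and SPRY1 at 1.09 ± 0.29 and 0.99 ± 0.30 (camera adjusted p = 0.243). In epithelial-rich spots its mean was 0.40, with 9 of 13 members above 0 and 1 past the list-alone threshold (camera adjusted p = 0.0327, and adjusted p = 0.597 with an estimated correlation).

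Interferon, antigen presentation and lymphocyte lists had means below 0 over all spots, with no single member past a threshold, while the mast cell list lay above 0 and the neutrophil list was not called (mean 0.07, camera adjusted p = 0.804). All 18 type I interferon genes lay below 0, with a mean of -0.82. CXCL10, a chemokine for T cells, had a change of -2.0 ± 0.62, OAS2 -1.06 ± 0.42 and IFIT2 -1.26 ± 0.52, and 0 of 18 passed over the list alone. The list shifted down in camera (adjusted p = 2.74e-11, and adjusted p = 0.527 with an estimated correlation), but 2 of 5 patients had a mean above 0. The interferon mean per patient was -0.80, and -1.13 to -0.332 without one replicate. In epithelial-rich spots the mean over interferon members was -1.06 (camera adjusted p = 4.32e-11, and adjusted p = 0.597 with an estimated correlation). The mean per patient there was -0.86, and -1.16 to -0.297 without one replicate, with 3 of 5 patients above 0. Where epithelial exceeded fibroblast UMIs, a setting with very few counts in some biopsies, the interferon list was at 1.47. The 7 tested genes of MHC class I antigen presentation all lay below 0, with a mean of -0.50 and TAP1 at -0.65 ± 0.30. The list shifted down in camera (adjusted p = 7.17e-05, and adjusted p = 0.527 with an estimated correlation). The MHC class I mean per patient was -0.48, and -0.799 to -0.341 without one replicate. All 14 T cell genes lay below 0, with a mean of -0.84, and 1 of 5 patients had a mean above 0. The T cell mean per patient was -0.49. Without replicate 1 it was -0.0883 and the T cell list was not called. CD2 was at -1.19 ± 0.35, TRAC at -1.04 ± 0.42 and CD6 at -1.02 ± 0.44 (camera adjusted p = 1.61e-05, and adjusted p = 0.527 with an estimated correlation). Of 12 cytotoxic genes 11 lay below 0, with a mean of -0.65, CCL5 at -1.23 ± 0.39 and CST7 at -1.11 ± 0.35. The list shifted down in camera (adjusted p = 3.15e-08, and adjusted p = 0.527 with an estimated correlation). The cytotoxic mean per patient was -0.55, and -0.824 to -0.343 without one replicate. For the lymphoid chemokine list 6 of 7 lay below 0, with CCL21 at -1.79 ± 0.79 (camera adjusted p = 0.00264, and adjusted p = 0.527 with an estimated correlation). The lymphoid chemokine mean per patient was -0.58. Without replicate 1 it was -0.125 and the list was not called.

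B cell genes had a mean of -1.07 and macrophage genes of -0.31 over all spots, and both lists shifted down in camera (adjusted p = 0.0296 and 0.0319, and adjusted p = 0.622 and 0.681 with an estimated correlation). Both directions depended on single patients. The B cell and macrophage means per patient were -0.55 and -0.14. Without replicate 1 they were 0.46 and 0.05, above 0. The macrophage mean was above 0 without replicate 3 or 4 as well. Plasma cell genes were not called (mean -0.26, camera adjusted p = 0.361). Hemoglobin genes were the most strongly lowered list. HBA2, HBB and HBD had changes of -3.85 ± 1.20, -3.60 ± 1.28 and -1.85 ± 0.58. Of these, 3 of 3 fell adjusted over the list alone (camera adjusted p = 6.59e-06, and adjusted p = 0.432 with an estimated correlation). The hemoglobin mean per patient was -2.68 ± 2.76 (SD, n = 5), above 0 in 1 of 5. Endothelial genes had a mean of -0.32, with 11 of 13 below 0 (camera adjusted p = 0.000216, and adjusted p = 0.527 with an estimated correlation). The endothelial mean per patient was -0.28. Without replicate 1 it was -0.0277 and the endothelial list was not called. Adipocyte genes lay below 0 for 11 of 11, with a mean of -0.94 and a spread between patients of 3.51 (SD, n = 5; camera adjusted p = 0.0483, and adjusted p = 0.681 with an estimated correlation). The adipocyte mean per patient was -0.48. Without replicate 1 it was 0.44, above 0, and the call was lost without replicate 1, 3 or 4. Fibroblast genes had a mean of -0.005 and were not called (camera adjusted p = 0.276).

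Estrogen receptor targets split, with 13 of 25 members above 0 and 12 below over all spots (mean 0.13, median 0.02, camera direction down, adjusted p = 0.982). Among them AREG, an EGF receptor ligand, had a change of 1.45 ± 0.46, the immediate early gene EGR3 of 2.23 ± 0.75 and NPY1R of -1.70 ± 0.55, and 0 passed over the list alone. In epithelial-rich spots the mean over members was -0.08 and the mean per patient 0.23 ± 1.25 (SD, n = 5), opposite in sign (camera adjusted p = 0.293). Proliferation genes lay above 0 for 24 of 28 members over all spots, with a mean of 0.33. The list shifted up in camera (adjusted p = 0.0124, and adjusted p = 0.681 with an estimated correlation), with a mean above 0 in 3 of 5 patients and 0 members past the list-alone threshold. The proliferation mean per patient was 0.48 ± 1.08 (SD, n = 5), and 0.198 to 0.745 without one replicate. The call was lost without replicate 1, 4 or 5. In epithelial-rich spots 9 of 22 lay above 0, the mean over members was -0.10 and the mean per patient 0.27 (-0.126 to 0.72 without one replicate), and the list was not called (camera adjusted p = 0.99). The epithelial list had a mean of 0.32 over all spots, with 8 of 12 above 0 and 1 member past the list-alone threshold (camera adjusted p = 0.0436, and adjusted p = 0.622 with an estimated correlation). The epithelial mean per patient was 0.36, and 0.179 to 0.508 without one replicate.

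With the preset correlation, camera called 18 of the 33 lists that could be tested over all spots and 7 of 27 in epithelial-rich spots. With an estimated correlation it called 0 in both, and fry, which asks whether a list's genes move one way on balance, called 0 in both.

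**Figure D2:**
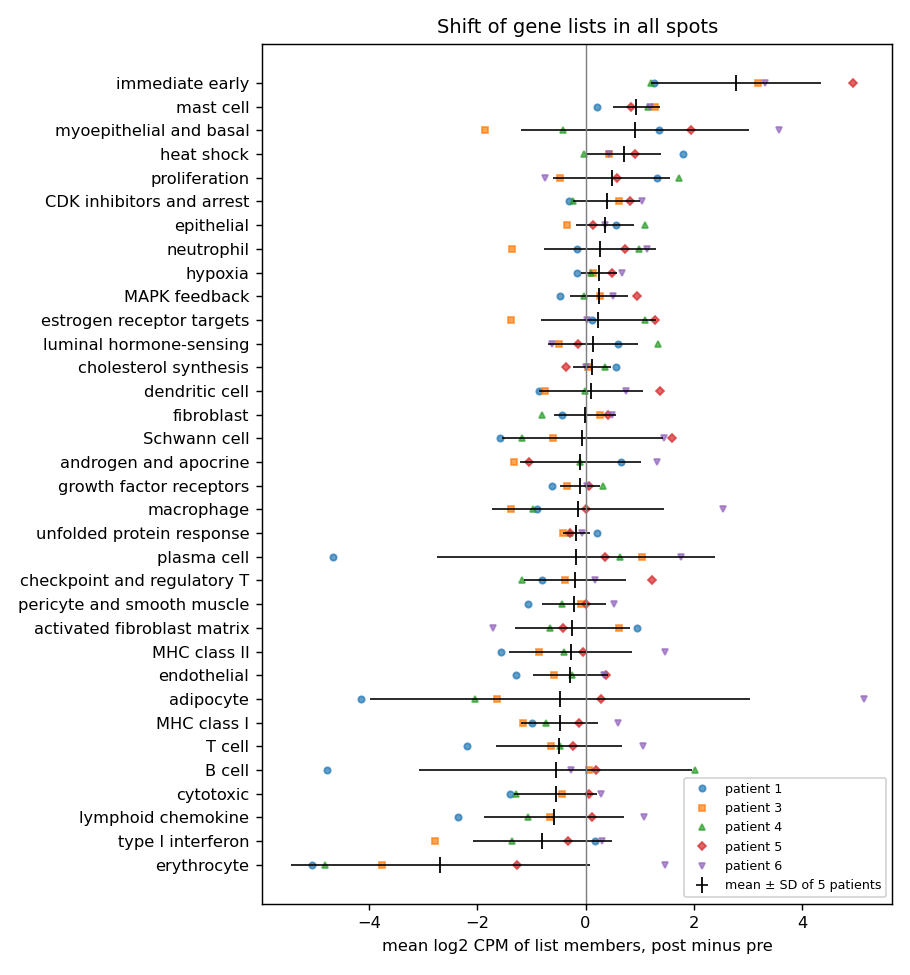
Mean log2 CPM of list members after minus before therapy (horizontal axis) for 34 lists over all spots, one point per patient, with the mean and SD of 5 patients. The immediate early list lies above 0 in all 5 patients, and most immune lists spread across 0.

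In the antibody layer PCNA, a clamp of the DNA replication fork, had the largest change. Its tags went from 0.941 ± 0.663 to 4.49 ± 3.77 times the mean isotype control (SD, n = 5), a log2 change of 2.29 ± 0.66 (± SE), higher in 5 of 5 pairs. CEACAM8, a granulocyte marker, went from 0.288 ± 0.074 to 1.35 ± 1.40 times isotype (1.66 ± 0.52, higher in 4 of 5 pairs). Before therapy neither PCNA nor CEACAM8 lay above the background on average, so the size of these 2 changes is uncertain. PECAM1, an endothelial marker, had a log2 change of -0.69 ± 0.22, from 3.83 to 2.37 times isotype. CD8A, of cytotoxic T cells, had -0.66 ± 0.22, from 3.65 to 2.14, and PTPRC_2, one of 2 antibodies against the leukocyte antigen CD45, -0.57 ± 0.21, from 2.50 to 1.64. Over isotype all 3 were lower in 5 of 5 pairs. As a share of all antibody tags each of the 3 was higher after therapy in 1 of 5 pairs. The other CD45 antibody, PTPRC_1, had a smaller change over isotype, -0.29 ± 0.25, and was higher in 1 of 5 pairs.

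None of the 31 antibodies passed in limma after adjustment (adjusted p = 0.173 for PCNA, CEACAM8, PECAM1 and CD8A, and 0.183 for PTPRC_2), with 7 at an unadjusted p below 0.05. In edgeR with trimmed-mean scaling of recovered tags 0 were called (4 at an unadjusted p below 0.05), and the exact sign-flip test cannot call any. The median antibody moved by -0.29 on the log2 scale over isotype and by -0.09 with trimmed-mean scaling, so decreases of this size depend on the scaling. With the sections of a specimen summed, PCNA passed (limma adjusted p = 0.0475, log2 change 2.78).

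**Figure D3:**
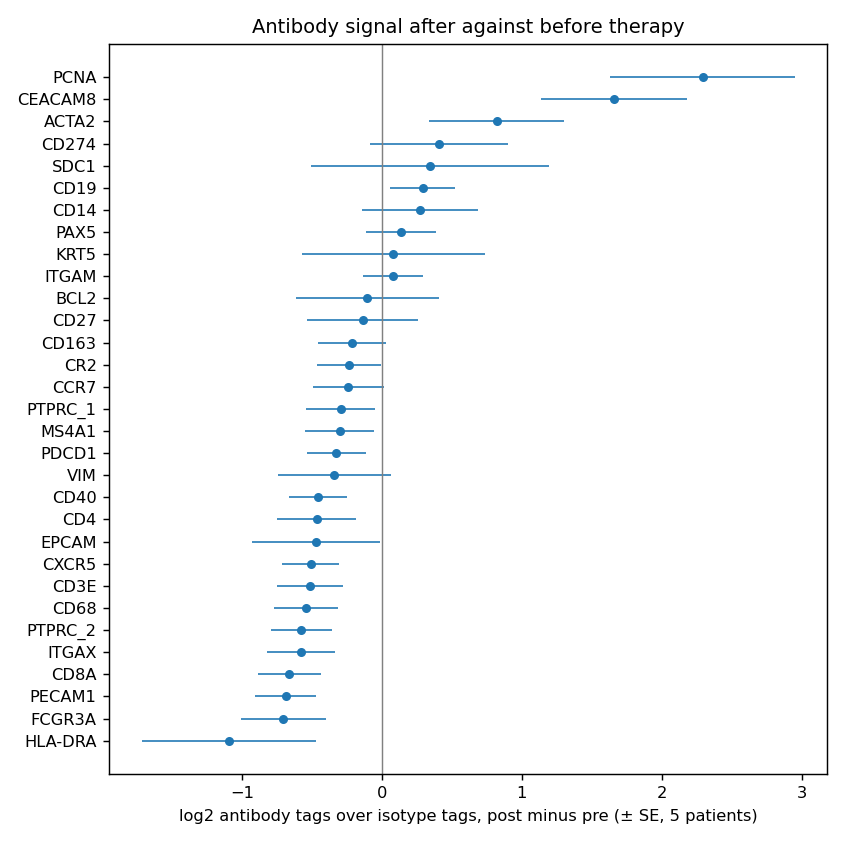
Log2 antibody tags over mean isotype tags, after minus before therapy (horizontal axis), with ± SE over 5 patients for each of 31 antibodies. PCNA and CEACAM8 lie highest, at 2.29 and 1.66, and none passed after adjustment.

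Antibody and transcript changes of the same marker were weakly related. Across 25 markers, which are not independent replicates, Pearson's r was 0.312 (permutation p = 0.121) and Spearman's rho 0.334 (permutation p = 0.103). The signs were the same for 17 of 25. Without the 2 antibodies farthest from the median, r was 0.335. PCNA transcript had a log2 change of 0.01 ± 0.30.

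Over the spots of one library, antibody and transcript of a marker followed each other to different extents. Spearman's rho averaged 0.329 for ACTA2 (smooth muscle actin), 0.299 for VIM (vimentin), 0.231 for EPCAM (epithelial adhesion molecule) and 0.226 for the apoptosis regulator BCL2, each above 0 in 10 of 10 libraries. It was -0.083 for CD40 and -0.051 for PTPRC_2. The median rho over markers was 0.103 ± 0.044 before and 0.027 ± 0.024 after therapy (SD, n = 5), lower in 5 of 5 pairs (exact sign-flip test, two-sided p = 0.0625, the smallest that 5 pairs allow). These medians cover more markers after therapy than before. With only the markers that had a value in both libraries of a pair, a setting chosen after the results were seen, the medians were 0.103 ± 0.044 and 0.089 ± 0.072, higher after therapy in 2 of 5 pairs (exact sign-flip test, p = 0.8125), so the difference depended on the markers covered. With raw counts of both it was 0.190 and 0.097, lower in 4 of 5 pairs (exact sign-flip test, p = 0.1875).

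The relation of epithelial and stromal transcripts over spots varied between patients. In spots thinned to 500 UMIs, rho between the epithelial and fibroblast lists was -0.229 ± 0.158 before and -0.190 ± 0.253 after (SD, n = 5), and between the epithelial and macrophage lists -0.157 ± 0.218 and -0.232 ± 0.064. The smallest p of 8 pairs of lists was 0.375 (exact sign-flip test, adjusted p = 0.929), and with 5 pairs this test could call none. Without thinning, rho between the epithelial and macrophage lists was 0.088 ± 0.131 before and -0.135 ± 0.237 after therapy, lower in 5 of 5 pairs (exact sign-flip test, p = 0.0625, adjusted p = 0.5). That setting also took in spots under 500 UMIs and used list shares. Its other sign before therapy therefore cannot be put down to thinning alone. The epithelial and fibroblast lists were then at -0.071 ± 0.142 and -0.092 ± 0.369, nearer 0 than with thinning.

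Moran's I is high for a patchy marker. After therapy it was largest for VIM (0.517 ± 0.226 before, 0.559 ± 0.239 after; SD, n = 5), ACTA2 (0.372 ± 0.132 and 0.524 ± 0.126) and KRT5 (0.342 ± 0.102 and 0.450 ± 0.140). Its median over antibodies was 0.197 ± 0.080 before and 0.241 ± 0.096 after, higher in 3 of 5 pairs (exact sign-flip test, p = 0.25). The isotype controls, the background, went from 0.084 to 0.135, higher in 5 of 5 pairs (exact sign-flip test, p = 0.0625).

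The 2 sections filed with one specimen were no more alike than specimens of different patients. Across genes, Pearson's r of log2 CPM was 0.727 and 0.797 between first section and rep library (2 specimens, no test), and 0.723 to 0.893 (median 0.806) over 10 pairs of post libraries of different patients. The SD of the log2 difference was 1.19 and 1.45, against a median of 1.21 between patients. In a check of labels, 2 libraries followed another specimen more closely than the one they were filed with, which bears on the settings that use the rep libraries. Depth was not matched for r, the SD or this check, and a gap in depth can lower r. The first section and the rep library held 9604793 and 994838 UMIs for replicate 4, and 3388458 and 5593524 for replicate 5.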

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

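Tests of explanations in this part were chosen after the results were seen, apart from the test at the edge of the smaller spot mask of replicate 2. Of 76 sets of 5 values, 4 held a value far from the others, and chance gives about 1 in 20. Pre replicate 3 had the most RNA of the biopsies, 2846636 UMIs against 921546 in the next. Post replicate 5 covered the fewest spots of the surgical specimens, 4351 against 4824 in the next. The plasma cell list shifted by -4.67 over all spots in patient 1, against 0.36 or more in the other 4. The T cell list shifted by 2.09 in epithelial-rich spots in patient 6, against -0.70 or less in the others.

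Immediate early genes were higher after therapy in 5 of 5 patients, by a mean of 3.01 in epithelial-rich spots. Depth alone is argued against: with every library thinned to the shallowest total over all spots, the mean shift was 2.49 ± 0.66 (SE, 5 pairs). More of another cell type is argued against by its markers, since over all spots, where its mean was 2.78, the list exceeded even the mast cell list, the nearest, by 1.84 ± 0.67 (SE), in 5 of 5 patients, though it exceeded the myoepithelial list in only 3 of 5 and the adipocyte and B cell lists in 4 of 5. The kind of specimen stays open as well, since 0 pairs hold the same kind of specimen on both sides. The time from loss of blood supply to fixation and other handling of surgical tissue cannot be told apart from therapy, which remains untested. The shift of 2.26 and -3.96 between sections filed with the same specimen shows that the list can differ between libraries filed under the same therapy, by less than the mean shift in one case and by more in the other. Both rep libraries were closer to another specimen than to their own, in a check that did not match depth.

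For these comparisons, 16 splits part every pair, so no share under 0.05 can be reached. The mean shift of the immediate early list in epithelial-rich spots was 3.01 for the real split and 2.38 at most in the others, and 1 split was as large, the real one. The count of genes in epithelial-rich spots was 9 for the real split and 43 at most in the others (3 splits as large), which points to a structure of the samples, whose nature was not tested. Over all spots the counts of genes were 0 and 2 (16 splits as large). The counts of lists were 18 and 18 over all spots (2 splits as large) and 7 and 15 in epithelial-rich spots (12 as large). Antibody counts were 0 and 0 (16 as large).

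All spots of pre replicate 2 recurred in post replicate 2, and 0 RNA or antibody entries differed, as one library filed under both groups with 2 spot masks would give. The smaller mask might outline separate tissue within the same capture area, for example a biopsy placed beside a surgical section. At its edge, over 572 pairs of neighbouring spots, the log2 UMI step was 0.053, against a median of 0.0446 at shifted positions of the mask, and a share of 0.4 of 1000 positions had a step as large. Inside the smaller mask the spots had a median of 362 UMIs, against 733 in the other spots of post replicate 2. Whether regions of the same specimen would differ as much was not tested. These values decide neither way, and whether the deposited pair holds 2 specimens cannot be told apart from a filing error.

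PCNA antibody signal was higher after therapy in 5 of 5 patients without passing the adjusted threshold. A lower isotype background is argued against, since the share of PCNA among all antibody tags was higher by 2.44 ± 0.56 (SE) on the log2 scale. More PCNA transcript is argued against as well, within limits: the antibody change exceeded that of the RNA by 2.28 ± 0.72 (SE). This SE takes the 2 errors as independent, though both come from the same patients. Before therapy the antibody lay at 0.941 times isotype, not above background, and the 5 biopsies held only 271 PCNA UMIs. Protein level, antibody access and staining differences between slides stay open and untested.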

How the results depend on the processing

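Chosen after seeing the data were the alternatives with 12 libraries, edgeR on recovered tags, the same markers in both libraries, the protein-RNA relation without 2 antibodies, and leaving out replicates for depth, co-localisation, Moran's I and rho. Limma as the main test of antibodies was also taken up after the form of their values was seen. The other alternatives were fixed before. The alternative without replicate 2 is the set of values reported. The cause of the changes given here was not tested unless stated. Gene counts over all spots (0) became 1 with DESeq2 size factors, 34 with DESeq2, 7 with limma voom, 2 without a filter, 1 in spots of at least 200 UMIs, 2 with matched spot numbers, 6 after thinning (7153 genes tested) and 0 to 5 without one replicate. In epithelial-rich spots (9) they became 0 with all 12 libraries, 0 with 12 libraries less the shared spots, 29 with DESeq2, 22 without a filter, 5 after thinning (1061 genes tested), 15 in the top 10 percent of spots, 2 in the top 50 percent, 4 where epithelial exceeded fibroblast UMIs, and 7 to 16 without one replicate (16 without replicate 1). Without the replicate block 0 genes were called in both; list counts were then 16 and 6 and antibodies 0. Of the 9 genes, all 9 were also called by DESeq2, by limma voom and in the top 10 percent. In the top 50 percent 1 of the 9 was called, and 2 where epithelial exceeded fibroblast UMIs. The log2 changes of the 8 named in the report stayed positive, between 1.99 and 6.08.

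List counts fell from 18 and 7 to 0 and 0 with an estimated correlation and with fry, which allow for correlated members, and to 6 and 3 after thinning. Over all spots they were 10 to 17 without one replicate (10 without replicate 1). In epithelial-rich spots they were 3 with the rep libraries, 14 in the top 50 percent, 1 where epithelial exceeded fibroblast UMIs, and 5 to 13 without one replicate (13 without replicate 6). Antibody counts were 0 except 1 with both sections summed. The median antibody-transcript rho changed by -0.0656 with 12 libraries (exact sign-flip test, p = 0.03125), a value that needs the pair with shared spots and compares medians over different markers. It changed by -0.0140 with the same markers in both libraries of a pair. The difference in median Moran's I (0.0447) was 0.00724 without replicate 6 and 0.108 with the rep libraries, higher in 4 of 5 pairs. Section r at a log2 CPM of at least 5 was 0.56.

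List shifts that were called in one setting or the other changed sign as follows, and 68 more values of lists turned sign without a call. The values given are means per patient. Leaving out one replicate over all spots gave -1.19 to 0.46 for B cell, -0.70 to 0.93 for plasma cell, -0.86 to 0.14 for macrophage, -0.44 to 0.003 for pericyte, -1.94 to 0.44 for adipocyte, -0.16 to 0.28 for luminal and -0.54 to 0.0708 for activated fibroblast lists. Without a change of sign it gave -0.93 to -0.0883 for T cell, -0.49 to -0.0277 for endothelial and -1.05 to -0.125 for lymphoid chemokine lists over all spots, with the weakest value and no call in each case without replicate 1. In epithelial-rich spots it gave -0.61 to 0.19 for androgen, -0.13 to 0.61 for estrogen target, -1.18 to 0.0692 for T cell and -0.50 to 0.38 for macrophage lists. The activated fibroblast matrix list, all spots, was at 0.0195 with both sections summed. The main means per patient in epithelial-rich spots were 8.3e-05 for macrophage, 0.23 for endothelial and -0.37 for androgen lists. In the top 50 percent macrophage was -0.14 and endothelial -0.17. In the top 10 percent endothelial was -0.17 and androgen 0.23. The main means over members were already below 0 for macrophage (-0.21) and endothelial (-0.17). For these 2 lists no clear change of direction is shown by the choice of spots. Where epithelial exceeded fibroblast UMIs androgen was 1.05, interferon 1.47 and MHC class I 1.79. In that setting pre replicate 4 held 3900 UMIs in 9 spots and pre replicate 6 held 3813 UMIs in 4 spots. Most genes had few or no counts there before therapy, so these 3 values do not show a change of direction. The immediate early mean lay between 2.24 and 4.52 in all settings. Of the values of single genes in the settings, 2488 kept direction and call, 48 gained a call, 52 lost one, and 61 turned sign without a call.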

Other observations

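Over all spots the unfolded protein response list had a mean log2 change of -0.18, with 8 of 11 members below 0 (camera adjusted p = 0.0124, and adjusted p = 0.527 with an estimated correlation). Hypoxia genes had a mean of 0.21 (camera adjusted p = 0.237), cholesterol synthesis genes of 0.10 (adjusted p = 0.771) and growth factor receptor genes of -0.15 (adjusted p = 0.128). Genes of the basal and myoepithelial list varied between patients, with a mean per patient of 0.92 ± 2.11 (SD, n = 5; camera adjusted p = 0.0588). Androgen and apocrine genes in epithelial-rich spots had a mean of -0.54, with 5 of 7 members below 0 (camera adjusted p = 0.0327, and adjusted p = 0.597 with an estimated correlation). Their direction was not stable: the mean per patient was -0.37 ± 1.07 (SD, n = 5), above 0 in 3 of 5. Leaving out one replicate gave -0.61 to 0.19.

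Antibodies differed in how far they followed their own transcript over spots. SDC1 and PCNA had a mean rho of 0.178 and 0.172, each above 0 in 10 of 10 libraries, and CD68 of 0.183, above 0 in 9 of 10. For CD4 it was 0.009, above 0 in 4 of 10, and for ITGAM -0.026, above 0 in 3 of 9.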
